A study of Homo sapiens with 18 samples.

How the data were processed

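RNA sequencing of polyadenylated RNA was analysed for 18 libraries of LNCaP, a human prostate cancer cell line that grows in response to androgen. The libraries fall into 6 groups of 3, each sampled after 48 h. They received medium without conditioned medium (control) or medium conditioned by M0, M1 or M2 macrophages made from the THP-1 monocytic leukaemia line. The last 2 groups received M1 medium with DMSO (the solvent) or M1 medium with the IκB kinase inhibitor IKK16 at 0.7 μmol/l in the same solvent. Groups were taken from the labels. The labels number the replicates and do not say whether they are separate cultures, so every p-value measures only the spread between these samples, which may be technical.

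The authors deposited 1 table of expected counts per RefSeq transcript. Its values are multiples of 0.5, without normalisation. The submitters' processing notes name the human genome build hg38, Trimmomatic, BWA 0.7.17 and HOMER 4.10. The role of each tool, the treatment of reads that match several places and the use of strand are not given in the sources used here. A read that lies in several transcripts of a gene appears in each of them, so the transcripts of a gene were not added up. Of 70507 transcripts (53912 coding, 16595 noncoding), 69830 were named with an NCBI gene table of assembly GRCh38.p14, 344 with GENCODE 29 names, and 333, which held 0.088 to 0.109% of the counts of a library, had no name and stayed out. The transcript with the highest total stood for its gene, which gave 28101 genes, 12543 of them (44.6%) with several transcripts, and the counts were rounded to whole numbers. One transcript per gene means that a change in the transcript used can appear as a change in the level of the gene.

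Gene counts summed to between 24202741.5 and 33814818 per library, and the 10 most abundant genes held 2.84 to 3.4% of them. A gene with no count in a library is limited to 3 counts, which is 0.0887 to 0.124 CPM, the library-size-scaled count unit of edgeR's cpm function. Folds against a group at 0 were computed against that floor of 3 counts per library and are lower bounds. Reads amplified by PCR without molecular identifiers are not independent molecules, so floors cover counting error only. All pairs of replicates differed by more than sampling noise, with a chi-square per gene of 2.7 to 21.55 and a Pearson correlation of log2 CPM of 0.9928 to 0.995.

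Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter at its defaults on the 6 groups (17073 genes kept, 11028 left out), and the quasi-likelihood test on all 18 libraries with 1 mean per group. The groups share 1 estimate of the spread, with a common biological coefficient of variation of 0.0627. The 9 comparisons each used a Benjamini-Hochberg adjusted p under 0.05, two-sided, as the threshold, and counts were repeated for changes of at least 2-fold. The standard error (SE) of a log2 fold change is the fold change divided by the square root of F. CPM values are TMM-scaled means ± SD over 3 libraries.

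Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 20 lists within a comparison, and again with a correlation estimated for each list. The lists are NF-kB targets, chemokines and cytokines, stemness-associated genes, androgen receptor targets, type I interferon response, interferon gamma response and antigen presentation, JAK-STAT3 response, mesenchymal, luminal, basal and neuroendocrine genes, S phase and DNA replication, G2/M, p53 targets, cholesterol synthesis, unfolded protein and ATF4 response, hypoxia and glycolysis, TGF-beta and Wnt targets, macrophage markers and housekeeping genes. A list of 15 mitochondrially encoded genes had 2 members in the table and was not tested. Some genes stand in more than 1 list. Genes named in the text are NANOG, SOX2 and CD44 from the series title, the 6 genes with the largest rise and the 6 with the largest fall in M1 medium against control and in IKK16 against DMSO (4 and 4 elsewhere), and up to 3 changed members per direction of each list, or up to 2 of the most abundant where none changed. Genes picked for the size of their change had to be protein-coding, reach 1 CPM and show no overlap between the groups. The tests, comparisons, lists, naming rule and alternatives other than the one on transcript length were chosen before the data were examined.

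The alternatives were DESeq2 1.42.0, its median-of-ratios scaling within edgeR, no filter on low counts, a filter of 1 CPM in 3 libraries, and a fit of the 2 groups compared alone. Further alternatives were the replicate number as a block, the longest transcript in place of the most abundant, each library left out in turn, and, for lists, fry and the estimated correlation. fry tests whether the genes of a list move one way on balance, and its mixed form whether they change in either direction; neither compares a list with other genes. An alternative that removes from each library its smooth trend of counts on transcript length was added after the data were seen (lowess span 0.5, genes above a log2 CPM of 3, 15600 genes with a length). The edgeR and camera steps were tested on simulated counts with 200 genes changed. For M1 medium against control (16836 genes) they recovered 84.8%, 84.6% and 100% of genes changed 1.5-, 2- and 4-fold, with 5.2% false calls. For IKK16 against DMSO (16826 genes) they recovered 68.7%, 95.5% and 95.2%, with 8.5% false calls, and in both cases camera called the list that was raised and none of the 19 other lists. Each gene was drawn independently, so these simulations do not test camera on lists whose genes vary together. They also changed a far smaller share of genes than the 64.9% and 27.1% called in the real comparisons.

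Overlap from independent noise between comparisons with a common control was taken from 20 simulations of unchanged groups. Reads of near-identical or overlapping genes may be split or counted more than once, which makes the values of SAA2, C4A, C4B, PEG3, ZIM2, CSF1R and the HLA genes uncertain. Coordinates are from the GRCh38.p14 table. Transcript lengths are from the GENCODE release named above.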

Results

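Gene expression was measured in LNCaP prostate cancer cells kept for 48 h in medium conditioned by THP-1 macrophages that were unpolarised (M0), M1-polarised or M2-polarised, diluted 1:4. A control received the same medium without macrophage products. M1 medium was also given with IKK16, which inhibits the IκB kinases that release NF-kB into the nucleus, or with its solvent DMSO. Each of the 6 groups has 3 libraries, with 24202741.5 to 33814818 gene counts each. Principal components were computed only from the genes with the largest variance across the libraries. The first held 91.7% of the variance of these selected genes and separated the 3 groups with M1 medium from the other 3. The second, with 2.9%, separated the libraries with IKK16 from those with M1 medium alone or with DMSO. Of 17073 genes tested with edgeR, 5586 were higher and 5487 lower in M1 medium than in control (1748 and 1357 by at least 2-fold), against 1206 and 770 for M0 medium and 911 and 575 for M2 medium.

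**Figure D1:**
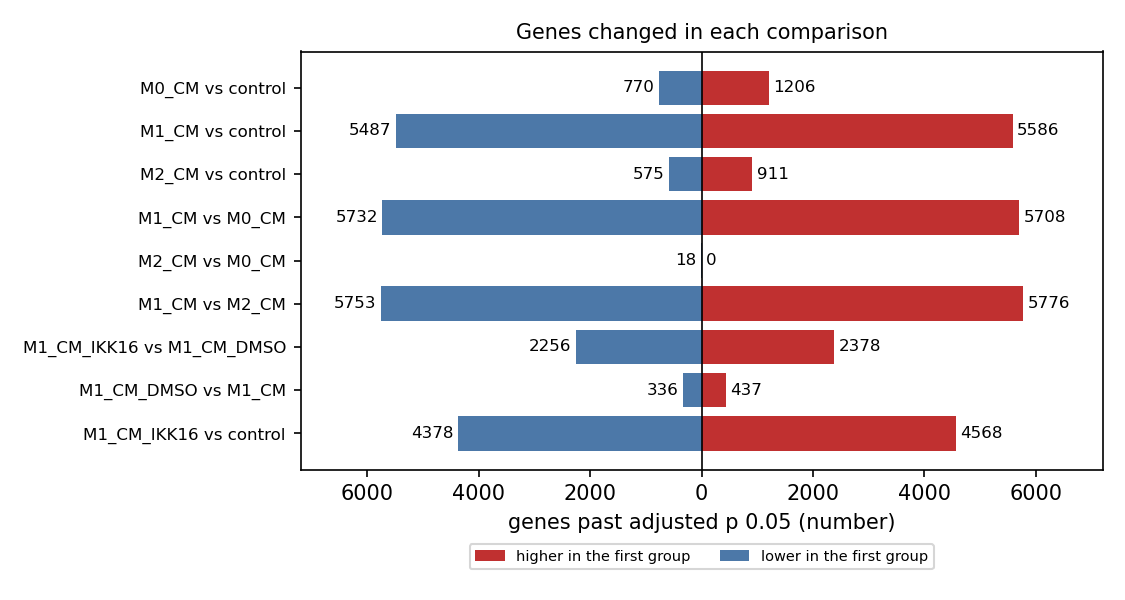
Number of genes (horizontal axis) past an edgeR adjusted p of 0.05 in each of 9 comparisons, with genes higher in the first group to the right and genes lower in it to the left. The bars of M1 medium against control reach 5586 and 5487 genes, those of M0 medium 1206 and 770, and those of M2 against M0 medium 0 and 18.

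The series title names NANOG, SOX2 and CD44, genes associated with stem-like cells, in connection with M1 macrophages and NF-kB. The study may have chosen them on these samples, so they are not taken as independent evidence. CD44 (chromosome 11, 35139171 to 35232402), a cell surface receptor for hyaluronan, stood at 0.559 ± 0.172 CPM in control, 0.354 ± 0.136 in M0, 4.50 ± 0.417 in M1 and 0.292 ± 0.108 in M2 medium (SD, n = 3). It rose 7.99-fold in M1 medium over control (log2 fold change 3.00 ± 0.24 SE, edgeR adjusted p = 1.77e-10), and it was also higher than in M0 medium (3.68 ± 0.27) and in M2 medium (3.92 ± 0.28, edgeR adjusted p = 1.31e-11). With IKK16, CD44 was 2.31-fold lower than with DMSO (1.27 ± 0.452 against 2.91 ± 0.235 CPM, log2 fold change -1.21 ± 0.23, edgeR adjusted p = 0.000414). It was still above the control, which had no DMSO (1.17 ± 0.30, edgeR adjusted p = 0.00217). CD44 also stood lower with DMSO than in M1 medium alone, a difference that did not pass (log2 fold change -0.62 ± 0.19, edgeR adjusted p = 0.0621). That difference passed edgeR without a filter (adjusted p = 0.0393), in a fit of the 2 groups alone, with the length trend removed and without M1 replicate 3. The differences of CD44 from control in M0 medium (-0.68, edgeR adjusted p = 0.247) and M2 medium (-0.92, edgeR adjusted p = 0.138) did not pass the threshold. SOX2 (chromosome 3, 181711925 to 181714436), a pluripotency transcription factor, had 5 counts in all in the M1 libraries, 6 with DMSO, 1 with M2 medium and 0 in the control, M0 and IKK16 libraries, too few to pass the filter. Without a filter its edgeR adjusted p was 0.0797 for M1 medium against control, 0.304 for M1 against M2 medium and 0.12 for IKK16 against DMSO. Adjusted over the title genes alone, of which 2 had counts, the edgeR p of SOX2 was 0.0399, 0.197 and 0.0291. The adjustment had been planned over all 3 title genes, which would give larger values. NANOG (chromosome 12, 7789402 to 7799146), also a pluripotency factor, had 0 counts in all 18 libraries, which allows 0.0887 to 0.124 CPM in each. Its near-identical copy NANOGP8 had at most 1 count per group, so hardly any reads were counted under this copy. Whether NANOG reads were discarded or counted under other copies remains uncertain.

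**Figure D2:**
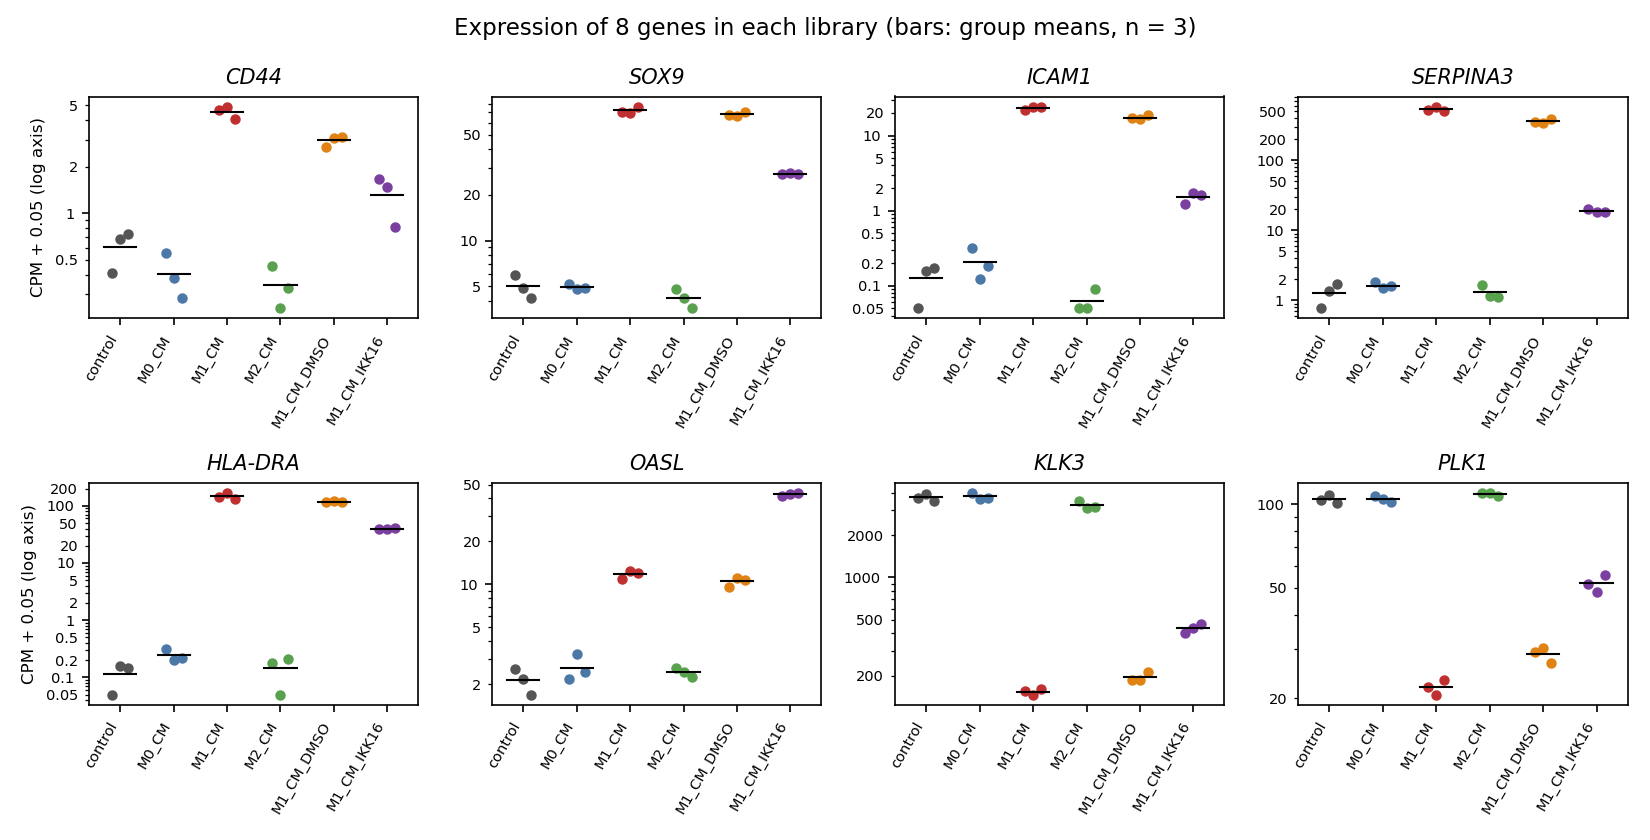
Expression of 8 genes in each library (points; CPM + 0.05 on log axes) and group means (bars, n = 3). ICAM1 lies at 23.4 CPM in M1 medium and 1.47 with IKK16, KLK3 at 3710 in control and 154 in M1 medium, and OASL, at 42.9 with IKK16, lies above all other groups.

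M1 medium raised inflammatory and interferon-induced genes. CHI3L2, a chitinase-like secreted protein, reached 171 ± 11.8 CPM from 0 counts in control, at least 1730-fold higher. CCL20, a chemokine for lymphocytes and dendritic cells, was at least 271-fold higher (26.9 ± 2.52 CPM). SERPINB7, an epithelial protease inhibitor, was at least 218-fold higher (21.5 ± 2.5), and complement C3 at least 153-fold (15.1 ± 0.997). Among the 25 NF-kB targets tested, 24 rose and none fell, also when adjusted over the list alone (camera adjusted p = 4.54e-60). LCN2, an iron-sequestering antibacterial protein, rose to 456 ± 25.1 from 0.145 ± 0.0599 CPM, and ICAM1 (chromosome 19, 10271120 to 10286615), an adhesion molecule for leukocytes, to 23.4 ± 1.27 from 0.0765 ± 0.0669 CPM. Of 17 chemokines and cytokines, 14 rose and 1 fell (camera adjusted p = 3.29e-12). CXCL8, which attracts neutrophils, was at 13.8 ± 2.69 against 0.044 ± 0.019 CPM, and TNF at 9.48 ± 0.72 against 0.0668 ± 0.0364 CPM.

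Of 36 genes of the interferon gamma response and antigen presentation, 34 rose in M1 medium and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.08e-57). HLA-DRA, the alpha chain of an MHC class II molecule, was at 148 ± 18.8 against 0.0661 ± 0.0576 CPM, and GBP4, an interferon-induced GTPase, at 20.4 ± 0.574 against 0.0783 ± 0.0826 CPM. The member that fell was CD274, which encodes the checkpoint ligand PD-L1, at 1.82 ± 0.606 against 6.7 ± 0.831 CPM (log2 fold change -1.89 ± 0.18, edgeR adjusted p = 1.91e-09). In the type I interferon list 25 of 31 genes rose and 1 fell (25 and 2 adjusted over the list alone; camera adjusted p = 8.03e-14). The antiviral synthetase OAS2 was at 4.77 ± 0.335 against 0.0653 ± 0.0319 CPM, and USP18, which removes ISG15 from proteins, was 2.17-fold lower. Of 20 JAK-STAT3 response genes, 15 rose and 3 fell (camera adjusted p = 3.78e-10). SERPINA3 (chromosome 14, 94612391 to 94624053), an acute-phase protease inhibitor, rose 427-fold to 532 ± 44.1 CPM, and SOCS2, a feedback inhibitor of cytokine signalling, fell by 1.64 on the log2 scale.

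Androgen receptor targets fell in M1 medium. Of 24 tested, 20 were lower and 2 higher (20 and 3 adjusted over the list alone; camera adjusted p = 8.55e-38), with a median log2 fold change of -1.78. KLK3 (chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, dropped from 3710 ± 209 to 154 ± 6.76 CPM (log2 fold change -4.59 ± 0.07, edgeR adjusted p = 7e-24). KLK2 (chromosome 19, 50873439 to 50880567), a related secreted protease, was 35.6-fold lower. The largest falls among genes reaching 1 CPM were those of CHRNA2, a nicotinic acetylcholine receptor subunit (-7.04 ± 0.20), the desmosomal genes DSG1 (-5.82 ± 0.29) and PKP1 (-5.62 ± 0.49), GHRHR (-5.72 ± 0.41), KRT14 (-5.65 ± 0.42) and HRNR (-5.63 ± 0.59), all log2 fold changes.

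Cell cycle genes fell as well. In M1 medium 25 of 26 S phase and DNA replication genes and 26 of 26 G2/M genes were lower, with the same counts adjusted over the lists alone. Their median log2 fold changes were -1.33 and -2.10 (camera adjusted p = 1.44e-24 and 6.8e-41). KIF20A, a kinesin of cytokinesis, was 5.54-fold lower (18.7 ± 1.94 against 104 ± 1.75 CPM), the mitotic kinase PLK1 4.75-fold lower (21.9 ± 1.35 against 104 ± 3.57 CPM) and E2F1, a transcription factor of S phase entry, 4.45-fold lower. Of 25 p53 targets, 18 rose and 3 fell (camera adjusted p = 0.00326), including the cell cycle inhibitor CDKN1A (log2 fold change 1.56 ± 0.05) and the pro-apoptotic BBC3 (1.64 ± 0.10).

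Lists of cell identity moved in part. Of 18 stemness-associated genes, 9 rose and 6 fell in M1 medium, and the list as a whole did not pass (camera adjusted p = 0.216). SOX9, a progenitor transcription factor, rose 14.7-fold to 72.3 ± 3.76 CPM. TERT, the catalytic subunit of telomerase (-2.61 ± 0.21), the histone methyltransferase gene EZH2 (-1.09 ± 0.06) and the integrin gene ITGA6 (-1.01 ± 0.08) fell. Mesenchymal genes rose as a list, with 9 higher and 4 lower of 18 (camera adjusted p = 0.00832). Fibronectin FN1 was 11.5-fold higher (5260 ± 191 CPM) and the matrix protease MMP7 reached 344 ± 32.4 CPM. TWIST1, a transcription factor of mesenchymal transition, fell by 1.96 on the log2 scale. Of 12 basal genes, 9 rose and 1 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.00289), with the laminin gene LAMB3 at 138 ± 11.1 against 0.411 ± 0.17 CPM, while KRT14 fell. The 21 luminal genes split into 11 higher and 9 lower (camera adjusted p = 0.123), with CD24 (4.85 ± 0.11) and ELF3 (3.70 ± 0.06) up and SPDEF (-1.92 ± 0.05) down. Among 10 neuroendocrine genes, 2 rose and 5 fell (camera adjusted p = 0.545), with TUBB3 up (1.27 ± 0.11) and PEG10 down (-4.39 ± 0.55).

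Metabolic and stress lists changed less clearly in M1 medium. Of 24 cholesterol synthesis genes, 5 rose and 15 fell (camera adjusted p = 0.0449, and adjusted p = 0.165 with an estimated correlation). This call was lost without M1 replicate 1 (camera adjusted p = 0.0524) and with the length trend removed (0.0564). TGF-beta and Wnt targets had 9 higher and 8 lower of 20 (camera adjusted p = 0.0395 upwards, adjusted p = 0.226 with an estimated correlation, and 0.0626 without control replicate 3). Their median of -0.08 differed in sign from their mean of 0.57. ID1, an inhibitor of differentiation factors, rose 13.2-fold and PMEPA1, an inhibitor of TGF-beta signalling, was 2.66-fold lower. The hypoxia and glycolysis list (7 higher and 14 lower of 25, camera adjusted p = 0.084) and the unfolded protein and ATF4 list (12 higher and 7 lower of 24, camera adjusted p = 0.246) did not pass. EGLN3, an oxygen-sensing prolyl hydroxylase, rose (2.69 ± 0.08) and PDK1, which limits pyruvate oxidation, fell (-1.71 ± 0.08). The stress factor ATF3 rose (1.56 ± 0.06) while PHGDH, the first enzyme of serine synthesis, fell (-0.95 ± 0.04). Of 15 housekeeping genes, 3 rose and 8 fell (camera adjusted p = 0.997), and B2M, the light chain of MHC class I, was 7.55-fold higher. Macrophage markers were also higher in M1 medium, 6 of 10 tested against 2 lower (camera adjusted p = 0.00424). ITGAM, the integrin alpha M chain, stood at 19.9 ± 1.45 against 0.16 ± 0.161 CPM and S100A9, a calcium-binding protein of myeloid cells, at 19.1 ± 4.11 against 0.0909 ± 0.108 CPM. With an estimated correlation the calls of the NF-kB, chemokine, androgen receptor, both interferon, JAK-STAT3, mesenchymal, basal, S phase, G2/M, p53 and macrophage lists held, at adjusted p from 7.02e-09 to 0.039.

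**Figure D3:**
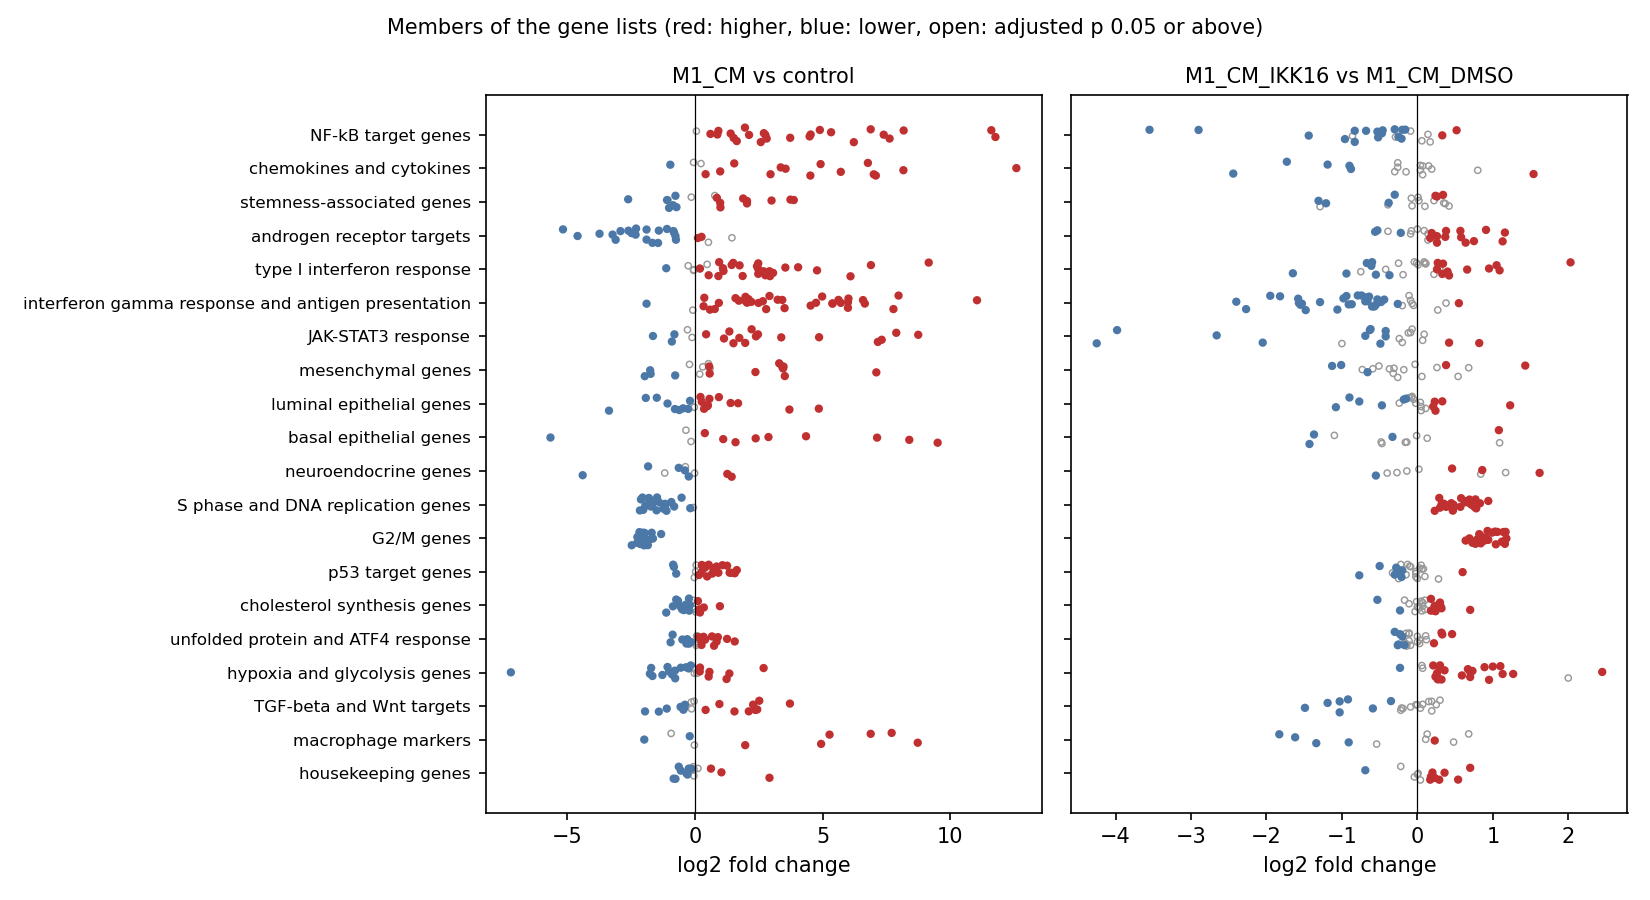
Log2 fold change (horizontal axes, edgeR) of each tested member of 20 gene lists for M1 medium against control and for IKK16 against DMSO, both with M1 medium; red and blue points passed an adjusted p of 0.05, open points did not. With M1 medium 24 of 25 NF-kB targets are red and 26 of 26 G2/M genes blue, and with IKK16 16 NF-kB targets are blue and all 26 G2/M genes red.

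Gene expression in M0 medium differed from control by small amounts, with 1206 genes higher and 770 lower (edgeR). These changes went in part with transcript length (Spearman correlation across genes -0.316), so the medium is not the only possible source, as described below. IL32, a proinflammatory cytokine, rose from 3.06 ± 0.36 to 6.53 ± 0.331 CPM (log2 fold change 1.09 ± 0.13, edgeR adjusted p = 9.34e-05). RELB, a subunit of NF-kB (1.04 ± 0.13), and PGK1, a glycolytic enzyme (0.48 ± 0.08), also rose, and the androgen-responsive FKBP5 fell (-0.39 ± 0.06). These genes were picked as examples after the values were seen, because they stayed called under every alternative. NF-kB targets rose as a list, with 7 of 25 higher (8 adjusted over the list alone; camera adjusted p = 9.38e-05, adjusted p = 0.00524 with an estimated correlation). Of 24 androgen receptor targets 8 fell (10 adjusted over the list alone; camera adjusted p = 0.000693, adjusted p = 0.0913 with an estimated correlation). Hypoxia and glycolysis genes rose in 9 of 25 cases (11 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.576 with an estimated correlation, fry adjusted p = 0.0793). Camera also called the housekeeping, p53 and interferon gamma lists. Those calls were lost with an estimated correlation (camera adjusted p from 0.0913 to 0.212). The edgeR counts rested on single libraries: they were 23 and 7 without control replicate 1, 55 and 14 without M0 replicate 1, and 579 and 283 without M0 replicate 3. They were 701 and 318 without control replicate 3 and 1509 and 1231 without control replicate 2. In a fit of the 2 groups alone they were 517 and 276.

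In M2 medium 911 genes were higher and 575 lower than in control (edgeR). These changes too went in part with transcript length (Spearman correlation across genes -0.265). A difference in RNA quality or preparation remains open, as described below. OAS1, an interferon-induced antiviral enzyme, rose (log2 fold change 1.07 ± 0.16, edgeR adjusted p = 0.00114), and RELB (0.78 ± 0.14) and the cyclin gene CCNB1 (0.40 ± 0.07) rose. The androgen- and hypoxia-responsive NDRG1 (-0.64 ± 0.10), the transcription factor gene MAF (-0.65 ± 0.07) and PMEPA1 (-0.52 ± 0.06) fell. These too were picked because they stayed called under every alternative. Of 24 androgen receptor targets 15 were lower (18 adjusted over the list alone; camera adjusted p = 8.16e-20, adjusted p = 0.000234 with an estimated correlation). Of 25 hypoxia and glycolysis genes 11 fell (14 adjusted over the list alone; camera adjusted p = 1.73e-10). In contrast, 9 of 26 S phase and 7 of 26 G2/M genes rose (11 and 9 adjusted over the lists alone; camera adjusted p = 2.02e-05 and 6.65e-05). Each of these 3 calls was lost at an adjusted p = 0.117 with an estimated correlation. Camera calls of the NF-kB, stemness, interferon gamma, luminal, p53 and TGF-beta lists were lost with it too (camera adjusted p from 0.0918 to 0.292). The edgeR counts fell to 99 and 63 without control replicate 1, 86 and 79 without M2 replicate 1 and 232 and 119 without M2 replicate 2. They rose to 1559 and 1087 without M2 replicate 3 and were 142 and 54 in a fit of the 2 groups alone.

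Set directly against each other, M0 and M2 medium differed in few genes. No gene was higher in M2 than in M0 medium and 18 were lower by edgeR at an adjusted p under 0.05. Of 17073 genes tested, 928 had an unadjusted edgeR p under 0.05, close to the number that this threshold gives where nothing differs. DESeq2 called 3 higher and 43 lower. The lower genes included BNIP3, a hypoxia-induced mitophagy receptor (log2 fold change -0.48 ± 0.07, edgeR adjusted p = 0.00412), GDF15, a stress-induced cytokine (-0.49 ± 0.07), NDRG1 (-0.59 ± 0.10), BHLHE40 (-0.63 ± 0.11) and PGK1 (-0.42 ± 0.08). Hypoxia and glycolysis genes were lower as a list, 12 of 25 (23 adjusted over the list alone; camera adjusted p = 4.74e-69, adjusted p = 0.000595 with an estimated correlation). So were androgen receptor targets, with 1 of 24 lower (9 adjusted over the list alone; camera adjusted p = 4.35e-18). Camera also called the stemness, interferon gamma, JAK-STAT3, luminal, S phase, G2/M, unfolded protein and housekeeping lists here. Those calls were lost with an estimated correlation (camera adjusted p from 0.0685 to 0.342). Of the 18 genes none stayed when M2 replicate 2 or M2 replicate 3 was left out, and the edgeR count of lower genes was 4 without M0 replicate 2, 3 without M0 replicate 3 and 35 without M2 replicate 1. The 5 genes named above lost their call without M2 replicate 2 and without M2 replicate 3.

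M1 medium was also compared directly with the media of M0 and M2 macrophages. Against M0 medium 5708 genes were higher and 5732 lower, and against M2 medium 5776 and 5753 (edgeR). CHI3L2 was at least 1580-fold higher than in M0 and at least 1670-fold higher than in M2 medium. LCN2 was at 456 ± 25.1 CPM against 0.413 ± 0.132 and 0.343 ± 0.0459 CPM. PIGR, which carries immunoglobulin across epithelia, was at 397 ± 4.53 against 0.179 ± 0.0621 CPM in M0 medium. KLK3 was lower by log2 fold changes of -4.62 ± 0.07 against M0 and -4.40 ± 0.07 against M2 medium, and SOX9 was higher by 3.88 ± 0.09 and 4.12 ± 0.10. In both comparisons 24 of 25 NF-kB targets and 34 of 36 interferon gamma genes were higher. In both, 20 of 24 androgen receptor targets and all 26 S phase and 26 G2/M genes were lower, with the same counts adjusted over each list alone (camera adjusted p from 1.88e-56 to 1.49e-26). These calls held with an estimated correlation (adjusted p from 1.01e-08 to 0.000306).

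Genes called against control were compared between media. M0 and M2 medium shared 663 higher and 292 lower genes, against 64.4 and 25.9 for independent lists. M0 and M1 medium shared 448 and 306 (394.6 and 247.5 for independent lists), and M1 and M2 medium 307 and 266 (298.1 and 184.8). The 307 shared higher genes of M1 and M2 medium were close to the number for independent lists, and the excess did not pass (one-sided Fisher's exact test p = 0.269). Unchanged groups simulated against the same controls shared 0 edgeR calls in 20 simulations. Groups without any change leave little to call. This 0 therefore does not show how many shared calls the common controls add where many genes are called. Part of any excess may come from the shared controls. The noise was drawn independently for each gene, without trends across a library such as those along transcript length. The simulations therefore cannot show the overlap, covariance or correlation that such trends in the controls would give. Across genes the covariance of log2 fold changes was 0.0562 for M0 and M2, 0.0873 for M0 and M1 and 0.0723 for M1 and M2, against simulated values of 0.0136, 0.0137 and 0.0138. The Pearson correlation was 0.576 for M0 and M2 (0.488 simulated). It was below the simulated value for M0 and M1 (0.226, 0.495 simulated) and for M1 and M2 (0.189, 0.501 simulated). Against control, the median absolute log2 fold change was 0.369 for M1, 0.137 for M0 and 0.13 for M2 medium, while the simulated groups were all unchanged. A larger spread on 1 side lowers a correlation whatever is shared, so the lower values with M1 medium do not show less sharing. For M0 and M2 the shared higher and lower genes were 12 and 6 without control replicate 1, 384 and 149 without control replicate 3, 44 and 11 without M0 replicate 1 and 338 and 127 without M0 replicate 3. They were 66 and 33 without M2 replicate 1, 183 and 67 without M2 replicate 2 and 1023 and 594 without M2 replicate 3. Without control replicate 2 these media shared 559 lower genes. For M0 and M1 they were 15 and 6 without control replicate 1, 37 and 7 without M0 replicate 1 and 217 and 120 without M0 replicate 3. The shared lower genes were 141 without control replicate 3 and 484 without control replicate 2. For M1 and M2 they were 41 and 40 without control replicate 1, 42 and 51 without M2 replicate 1, 87 and 57 without M2 replicate 2 and 504 and 429 without M2 replicate 3.

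In cells given M1 medium, 2378 genes were higher and 2256 lower with IKK16 than with DMSO (edgeR), 142 and 283 of them by at least 2-fold. SERPINA3 was 19.1-fold lower (18.8 ± 1.05 against 359 ± 23.5 CPM, log2 fold change -4.25 ± 0.10, edgeR adjusted p = 2.72e-19). ITIH4, an acute-phase plasma protein, was 14.3-fold lower, ICAM1 11.7-fold lower (1.47 ± 0.251 against 17.3 ± 1.15 CPM) and C3 7.44-fold lower. Of 25 NF-kB targets 16 fell and 2 rose (17 and 3 adjusted over the list alone; camera adjusted p = 5e-16). The mitochondrial superoxide dismutase SOD2 was 2.71-fold lower (653 ± 16.6 against 1770 ± 62.9 CPM), while BIRC3, an inhibitor of apoptosis (0.33 ± 0.05), and the immediate early gene IER3 (0.52 ± 0.13) rose. Interferon gamma genes fell in 28 of 36 cases and rose in 1 (29 and 1 adjusted over the list alone; camera adjusted p = 2.46e-47), among them GBP2, a GTPase of cell-autonomous defence, 4.84-fold. JAK-STAT3 genes had 10 lower and 2 higher of 20 (12 and 2 adjusted over the list alone; camera adjusted p = 1.53e-11).

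Type I interferon genes did not move together with IKK16: 11 of 31 rose and 7 fell (12 and 9 adjusted over the list alone; camera adjusted p = 0.0796). OASL, an interferon-induced protein related to OAS2, rose 4.08-fold (42.9 ± 0.971 against 10.5 ± 0.777 CPM), IFIT1, which binds foreign RNA, 2.08-fold and the antiviral RSAD2 2.13-fold. Chemokines and cytokines did not pass as a list (1 higher and 5 lower of 17, camera adjusted p = 0.0606): CXCL8 fell 3.31-fold and CCL5, a T cell chemokine, rose 2.91-fold. Androgen receptor targets rose in 13 of 24 cases and fell in 3 (14 and 3 adjusted over the list alone; camera adjusted p = 4.49e-06), with KLK3 at 437 ± 31.8 against 195 ± 15.9 CPM, 2.24-fold higher. All 26 S phase and all 26 G2/M genes were higher with IKK16, with median log2 fold changes of 0.52 and 0.90 (camera adjusted p = 5.21e-27 and 6.12e-61), among them HMMR, a spindle-associated hyaluronan receptor, 2.26-fold. Of 25 hypoxia and glycolysis genes 21 rose and 1 fell (camera adjusted p = 1.69e-18), with PDK1 2.42-fold higher. APLN, a peptide hormone, rose 4.47-fold.

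Of the other lists with IKK16, TGF-beta and Wnt targets had 7 of 20 lower (8 adjusted over the list alone; camera adjusted p = 0.000106), with ID1 2.05-fold and ID3 2.80-fold lower. Basal genes had 3 lower and 1 higher of 12 (camera adjusted p = 0.0162), with LAMB3 2.58-fold lower. Macrophage markers had 4 lower and 1 higher of 10 (camera adjusted p = 0.0314, adjusted p = 0.0912 with an estimated correlation, and 0.0567 without IKK16 replicate 2), including S100A9 3.55-fold lower. Luminal genes (5 higher and 6 lower of 21) and housekeeping genes (9 higher and 1 lower of 15) each had a camera adjusted p = 0.0477. Adjusted over the lists alone the counts were 5 and 7 and 9 and 2, and with an estimated correlation the camera results were adjusted p = 0.12 and adjusted p = 0.131. The luminal call was lost without DMSO replicate 1 (camera adjusted p = 0.0611) or 3 (0.0501) and without IKK16 replicate 1 (0.0506) or 2 (0.0816). The housekeeping call was lost without DMSO replicate 1 (0.0658) or 2 (0.0661) and IKK16 replicate 2 (0.0567) or 3 (0.0656), and with the scaling of DESeq2 (camera adjusted p = 0.053). With the length trend removed the macrophage (camera adjusted p = 0.051), luminal (0.0517) and housekeeping (0.0584) calls were lost. Among 18 stemness-associated genes 3 rose and 4 fell (camera adjusted p = 0.245), with SOX9 2.47-fold lower. The list calls for NF-kB, interferon gamma, JAK-STAT3, androgen receptor, S phase, G2/M, hypoxia, TGF-beta and basal genes held with an estimated correlation, at adjusted p from 8.49e-06 to 0.0391.

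Genes changed by M1 medium were often changed the other way by IKK16, in comparisons that share no library. Of 1748 genes raised at least 2-fold by M1 medium, IKK16 lowered 751 (43%, against 231 for independent lists; one-sided Fisher's exact test p = 2.52e-241) and raised 92. Of 1357 genes lowered at least 2-fold, IKK16 raised 589 (43.4%, against 189; one-sided Fisher's exact test p = 1.2e-172) and lowered 15. At any size of change, 1707 raised genes were lowered by IKK16 (738.1 for independent lists) and 1641 lowered genes were raised (764.3); genes are not independent, so these tests describe the lists. The median log2 fold change of these 1748 and 1357 genes with IKK16 against DMSO was -0.36 and 0.39, beside 1.88 and -1.57 for M1 medium against control. With IKK16, 1485 and 1179 of them were still called against the same control libraries in the direction of M1 medium. No group received IKK16 without M1 medium, so a reversal of the M1 effect cannot be told from a separate effect of IKK16.

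**Figure D4:**
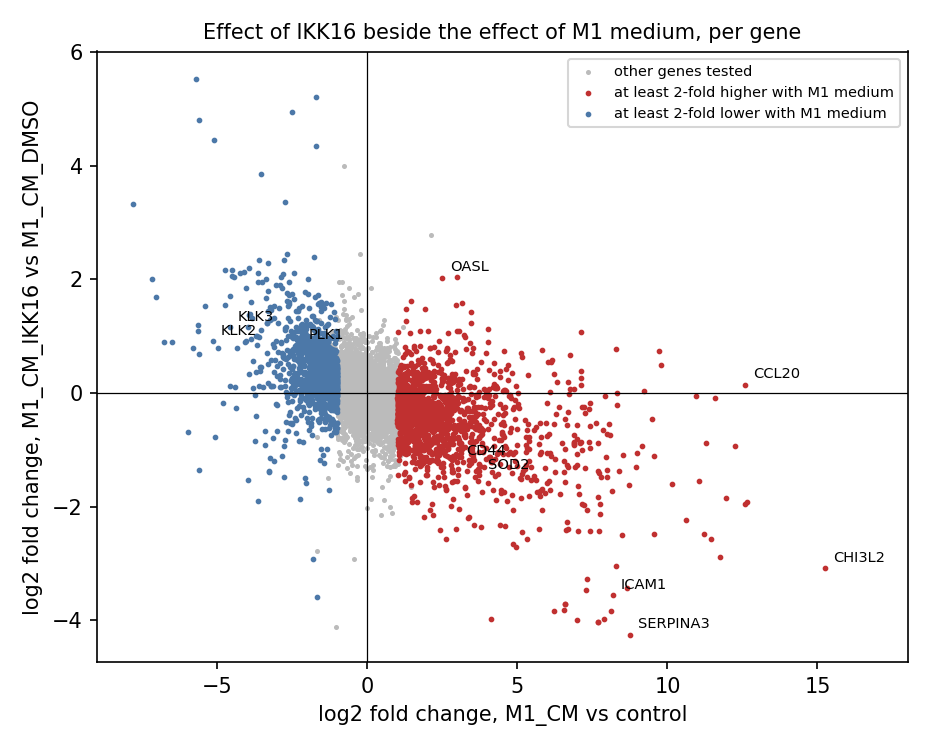
Each point is a gene, with its log2 fold change for M1 medium against control (horizontal axis) and for IKK16 against DMSO, both with M1 medium (vertical axis), as fitted by edgeR with a prior count. SERPINA3 and ICAM1, raised by M1 medium, lie at -4.25 and -3.55 on the vertical axis, KLK3 lies at -4.59 and 1.16, and OASL lies at 2.03 on the vertical axis.

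With IKK16 and M1 medium together, 4568 genes were higher and 4378 lower than in control (edgeR). The control had no DMSO, so this comparison joins M1 medium, inhibitor and solvent. CCL20 was at least 332-fold and CHI3L2 at least 155-fold higher than in control, and LCN2 stood at 384 ± 18 against 0.145 ± 0.0599 CPM. SERPINA3 was still 15.1-fold higher and KLK3 8.5-fold lower. Of 25 NF-kB targets 24 were higher and 1 lower, and of 24 androgen receptor targets 21 were lower and 1 higher, with the same counts adjusted over the lists alone (camera adjusted p = 1.86e-67 and 1.84e-47). All 26 G2/M genes were lower (camera adjusted p = 3.74e-17), and these 3 calls held with an estimated correlation at an adjusted p of 0.00156 or less.

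Expression in M1 medium with DMSO differed by small amounts from that in M1 medium alone. In M1 medium with DMSO 437 genes were higher and 336 lower than in M1 medium alone (edgeR). SOD2 (log2 fold change -0.37 ± 0.04, edgeR adjusted p = 5.71e-05), GBP1 (-0.79 ± 0.10) and SERPINA3 (-0.57 ± 0.08) were lower. PLK1 (0.40 ± 0.07), the replication licensing factor gene CDT1 (0.53 ± 0.08) and SLC45A3, a prostate transporter (0.36 ± 0.05), were higher. These examples were picked because they stayed called under every alternative. NF-kB targets (6 of 25 lower, 9 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.55e-05) and interferon gamma genes (6 of 36 lower, 11 adjusted over the list alone; camera adjusted p = 2.09e-10) fell as lists. S phase and G2/M genes rose, 10 and 6 of 26 each (14 and 9 adjusted over the lists alone; camera adjusted p = 1.93e-10 and 1.35e-09). The 4 calls held with an estimated correlation, at adjusted p from 0.0079 to 0.02. The edgeR counts were 72 and 97 without M1 replicate 1, 29 and 47 without M1 replicate 2, and 811 and 678 without M1 replicate 3. They were 42 and 68, 93 and 83 and 144 and 144 without DMSO replicates 1, 2 and 3. In a fit of the 2 groups alone they were 873 and 694.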

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

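All tests in this part were chosen after the results they bear on had been seen. Among the 11028 genes left out by the filter on low counts, some had 0 counts in the control libraries and over 9 in the 3 libraries of another group, a signal outside the comparisons and above the control level. There were 98 such genes in M1 medium, 72 in M1 medium with DMSO and 40 with IKK16, against 1 in M0 and 2 in M2 medium. The reverse, over 9 counts in control and 0 in the group, held for 28, 19, 25, 2 and 7 genes. Examples, picked after their values were seen, are IL34, a ligand of the CSF1 receptor (34 counts in M1 medium, 32 with DMSO and 16 with IKK16), TNFAIP6, a TNF-induced hyaluronan-binding protein (28, 12 and 2), and SLC26A9, an anion transporter (27, 21 and 11). They stood outside the edgeR fit reported above and were fitted only in the alternative without a filter.

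Each comparison was repeated on the 10 ways of splitting its 6 libraries into groups of 3, which are too few for a share under 0.05. For M1 medium against control the real split gave 11073 genes and the highest other split 0, for M1 against M0 medium 11440 and 0, for M1 against M2 medium 11529 and 0, and for IKK16 against DMSO 4634 and 0, all by edgeR. The values were 8946 and 0 for IKK16 against control and 773 and 0 for DMSO against M1 medium. For M0 medium against control the values were 1976 and 2, and for M2 medium against control 1486 and 680, with the real split the only 1 of the 10 to reach its count. For M2 against M0 medium 2 of the 10 splits gave as many genes as the real one: it gave 18 and another split 202, which points to a structure among these 6 libraries that the groups do not follow.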

How the results depend on the processing

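The transcript length alternative was added after the data were seen, the others before the data were examined. Counts for M1 medium against control, M0 or M2 medium, IKK16 against DMSO and IKK16 against control stayed within 1.5 times under every alternative. With a library left out they ranged from 5292 to 5442 higher and 5057 to 5302 lower for M1 against control and from 1763 to 2247 and 1671 to 1986 for IKK16 against DMSO. Fitting the 2 groups alone gave 517 higher and 276 lower genes for M0 medium against control, 142 and 54 for M2 medium against control, 3 and 2 for M2 against M0 medium and 873 and 694 for DMSO against M1 medium. In that fit M0 and M1 medium shared 186 higher and 133 lower genes, M0 and M2 92 and 19, and M1 and M2 39 and 36. DESeq2 gave 1241 lower genes for M0 and 871 for M2 medium against control, 3 higher and 43 lower for M2 against M0 medium, 753 and 510 for DMSO against M1 medium. It gave 472 and 549 shared lower genes for M0 and M1 and for M0 and M2. Without a filter M2 against M0 medium had 4 higher and 38 lower genes, and with the length trend removed DMSO against M1 medium had 664 and 533. With 1 library left out, which assumes that a group of 2 varies like the others, counts ran from 23 to 1509 higher and 7 to 1231 lower for M0 medium, 86 to 1559 and 63 to 1087 for M2 medium, and 0 to 1 and 0 to 35 for M2 against M0 medium. They ran from 29 to 811 and 47 to 678 for DMSO against M1 medium. Shared higher and lower genes ran from 15 to 547 and 6 to 484 for M0 and M1, 12 to 1023 and 6 to 594 for M0 and M2, and 41 to 504 and 40 to 429 for M1 and M2. All counts in these ranges rest on fewer samples, yet for M0 medium they reached 1509 higher genes against 1206 in the full fit. The low counts thus depend on which library was left out, and the cause was not tested. Changes of at least 2-fold, 20 higher and 7 lower for M0, 11 and 19 for M2 medium and 2 and 7 for DMSO, are as dependent on single libraries. CD44, not called between M2 and M0 medium, ran from -0.58 without M2 replicate 1 to 0.08 without M0 replicate 1, with 0.00 without M2 replicate 2 (log2 fold changes).

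Of 698 called results of named genes, 2 were lost and 677 held with DESeq2, 2 and 696 with its scaling, 5 and 693 with the longest transcript and 7 and 691 without a filter. With the stricter filter 0 were lost and 651 held, with the length trend removed 20 and 671, and in the fit of 2 groups 63 and 609; the rest had no value. Over all libraries left out in turn, 543 calls of named genes were lost and 3645 held, and 58 list calls were lost and 554 held. None was reversed. Of 102 list calls, 36 were lost with an estimated correlation, 7 and 4 with the directional and mixed fry tests, 2 with the other scaling and 8 with the length trend removed. The other scaling shifted the median log2 fold change by at most 0.0091. With the replicate number as a block, edgeR gave 5562 and 5457 genes for M1 medium against control, 2323 and 2224 for IKK16 against DMSO, 1201 and 815 for M0 medium and 886 and 572 for M2 medium. No count moved over 1.5 times, and 11 calls of named genes and 3 of lists were lost. The numbers do not pair the samples across all groups: of 45 pairs with the same number 13 correlated above 0.1 (range -0.503 to 0.513, median -0.014), and 6 libraries were closest to their own number. Among M0, M2 and DMSO libraries, singled out after the values were seen, every same-number pair correlated positively (0.065 to 0.513). Pairing among these groups is not excluded. Depth limits what can be said of NANOG, at 0 counts, and of SOX2, at 6 counts or fewer per group.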

Other observations

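All tests of explanations in this part were chosen after the results they bear on had been seen. Several lists not described above changed in part with IKK16 and did not pass as lists. Of 25 p53 targets 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0796). GDF15, a stress-induced cytokine, rose 1.52-fold to 4030 ± 268 CPM, and BBC3 (log2 fold change -0.77 ± 0.10), ZMAT3 (-0.50 ± 0.08) and CDKN1A (-0.30 ± 0.05) fell. Of 24 cholesterol synthesis genes 10 rose and 2 fell (camera adjusted p = 0.0816), with INSIG1, a regulator of sterol synthesis, up (0.32 ± 0.05). The neuroendocrine list had 3 higher and 1 lower of 10 (camera adjusted p = 0.0789), with the decarboxylase gene DDC up (0.86 ± 0.06) and TUBB3 down (-0.55 ± 0.11). Of 18 mesenchymal genes 2 rose and 3 fell (camera adjusted p = 0.169), with FN1 2.18-fold lower at 2100 ± 133 CPM. Of 24 unfolded protein and ATF4 genes 4 rose and 6 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.419), with ASNS, asparagine synthetase, up (0.33 ± 0.06) and XBP1 down (-0.26 ± 0.05).

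In the stemness-associated list, M1 medium with IKK16 differed from control in 15 of 18 genes, 9 higher and 6 lower with the same counts adjusted over the list alone (camera adjusted p = 0.361). KLF4, a reprogramming factor, was at 72.2 ± 0.443 against 19.6 ± 0.321 CPM. SOX9 was higher by 2.48 ± 0.10 and the chemokine receptor CXCR4 by 1.56 ± 0.29, and TERT was lower by a log2 fold change of -1.82 ± 0.20.

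The small changes in M0 and M2 medium went with transcript length, with a Spearman correlation of log2 fold change with length, across genes, of -0.316 for M0 and -0.265 for M2 medium against control and 0.072 for M1 medium. Single libraries of 1 group differed along length as much, from -0.072 to 0.557 in control, -0.545 to 0.161 in M0 and -0.491 to 0.302 in M2 medium, and an exact two-sided permutation test of these values gave p = 0.2 for M0 and p = 0.3 for M2 medium against control, where 0.1 is the smallest possible. With each library's length trend removed, 67.9% of the M0 calls (1271 of 1871) and 75.7% of the M2 calls (1048 of 1385) remained in the same direction. This argues against length, measured on the longest transcript of each gene, as the whole cause. Ribosomal precursor RNA (the RNA45S genes, singled out after the values were seen) stood at 2650, 5480 and 2440 CPM in the control, 2010, 1850 and 2810 in the M0 and 2140, 543 and 1600 in the M2 libraries, so each M2 library lay below each control library. Length bias may account for part of the calls, and a difference in RNA quality or preparation, which this order leaves possible for M2 medium, and a true effect of the media both remain open.

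Macrophage markers were higher in M1 medium, which raised the question of macrophages carried over with the medium. Such cells bring all their abundant transcripts, yet over all 26 listed markers, used after a smaller choice had been tried, the median was 5.5 counts in M1 libraries, 0.301% of the 1825 counts of ITGAM (15 in control), and TYROBP, CYBB, MNDA and PTPRC had 0. This argues against carried-over macrophages as the source of ITGAM. S100A9 (1749 against 8 counts), LYZ (209 against 5) and S100A8 (169 against 0) may instead be made by LNCaP cells in M1 medium, a hypothesis for which no further test was run. CSF1R, at 17894 and 20348 counts, may hold reads of another gene.

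The response to M1 medium was smaller in the libraries with DMSO. To keep the choice of genes apart from the libraries compared, genes were taken from IKK16 against control. Of 1210 at least 2-fold higher there, 70% were lower with DMSO than in M1 medium alone (median log2 fold change -0.123; 103 called lower and 9 higher by edgeR). Of 735 at least 2-fold lower, 63.8% were higher with DMSO (median 0.094). This argues against selection of genes on the same libraries as the cause. With the length trend removed 97.8% of the calls between DMSO and M1 medium remained (718 of 734). This argues against length, measured on the longest transcript of each gene, as the whole cause. An effect of DMSO and a separate preparation of that arm could each give this pattern and cannot be told apart, since every library with DMSO alone belongs to 1 group.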
